A study of Homo sapiens with 12 samples.

How the data were processed

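RNA-seq libraries were analysed from 3 established human non-small-cell lung cancer lines, PC9, HCC827 and H1975, each carrying either a vector that expresses ZNF263 or a control vector. Each line and vector was represented by 2 libraries, which gave 12 libraries in 6 groups. Per the labels' protocols, the cells were grown in DMEM and exposed to osimertinib in steps, RNA was extracted with TRIZOL, and libraries were made with a SMARTER mRNA-seq kit. Each library was assigned to its group by its cell line and genotype labels. The titles add OR to the name of each line, which the labels do not explain, and the lines are named here without it. The labels number the libraries of a group but do not say that they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

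The authors deposited expression as FPKM values (fragments scaled by gene length and by library size), with 1 column per library. Per the submitters' processing notes, the genome build was GRCh38.p13. The aligner, the counting tool, the gene annotation and any strand setting are not given in the sources used here. The PC9 columns held a value for every gene of the table, whereas 3410 genes had no value in HCC827 and 3366 had none in H1975. Among 314 genes with a mean of at least 1 FPKM in PC9 and no value in either other line, 245 carried only an older gene symbol, against 139 of 10514 such genes with values. PC9 was therefore treated as a table made separately from those of the other lines, and ZNF263 was compared with control only within a line. The spread of a gene was still shared by all lines, and the average and the tests between lines combine the within-line differences. Levels set side by side across lines come from separately processed tables. The table also held 27 entries whose gene names had been turned into calendar dates, and these were left out.

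Library totals were not given, so depth was read from the values themselves. For each gene, the smallest read numbers were sought that made its values whole multiples of the worth of 1 read, first with up to 20000 and then up to 300000 reads in the gene's first library. In the first pass whole reads were found for 99.5% of genes in PC9 (99.46), 99.5% in HCC827 (99.51) and 98.7% in H1975, against 0.18%, 0.16% and 0.11% when values were shuffled between genes. After the second pass 1 gene, AURKA, had no whole reads in PC9 and in HCC827, and no gene was left in H1975. For the gene with the median worth of a read, 1 FPKM stood for between 64.9 and 80.2 reads in the PC9 and HCC827 libraries and between 119.1 and 129.0 reads in the H1975 libraries. The recovery was tested on simulated data with the library factors given. It returned the reads of 100.0% of 500 simulated genes, up to a factor common to the libraries of a gene. Mean chi-square values between the 2 libraries of a group, over bins of read number, lay between 1.42 and 14.5. Sampling alone gives 1, so the libraries varied beyond sampling, and that excess may be technical. Each library was counted as a separate sample. At 10 to 50 reads they were 3.59 and 3.43 in H1975 and between 1.42 and 1.50 in the other lines, so the larger read numbers in H1975 were not taken to mean a higher precision.

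Values were analysed as log2(FPKM + 1), and a log2 change is on that scale, which understates the change of genes with low expression. Genes with at least 1 FPKM in 2 or more of the 12 libraries were kept. Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trended prior variance), with 1 mean per group and a spread shared by all 6 groups. The contrasts were ZNF263 minus control in each line and the mean of those 3 differences, tested on both sides, and an F test of whether the difference varied between lines. The Benjamini-Hochberg method was applied over all genes within a contrast, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene below comes from limma in this fit unless another fit is named. Numbers of shared calls were tested by Fisher's exact test, 1-sided, over genes tested in both lines, and adjusted over the 12 pairs of line and direction. The lines share no control libraries.

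Gene lists were written from textbook knowledge: ERBB receptors and ligands, MAPK output, STAT5 targets, mitosis and AURKA module, DNA replication, KRAB co-repressor and DNA methylation machinery, heparan sulfate synthesis and proteoglycans, bypass receptor tyrosine kinases, YAP/TEAD targets, epithelial, mesenchymal, apoptosis regulators, p53 targets, interferon response, antigen presentation, NF-kB and cytokines, unfolded protein response, ATF4 response, cholesterol synthesis, hypoxia and glycolysis, NRF2 targets, aldehyde dehydrogenases and drug efflux, nuclear-encoded oxidative phosphorylation, ribosomal proteins, lung epithelial lineage, squamous, fibroblast, neuroendocrine, immune cell and endothelial markers, mitochondrially encoded genes and replication-dependent histone genes. Lists with at least 5 measured genes were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. For each list the members called over all genes are given beside the number adjusted over the list alone. Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

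By that rule, ZNF263, EGFR, DNMT1, STAT5A, STAT5B and AURKA were named for every contrast. Also named were the 8 genes with the largest rise and the 8 with the largest fall among called genes that had a mean of at least 2 FPKM over the 12 libraries and whose libraries with ZNF263 both lay beyond both controls, in the line of the contrast or, for the average, in every line. From each list called by camera, or with at least 3 called members, up to 4 members with the smallest adjusted p were named. For the difference between lines, the 8 genes with the smallest p of the F test were named. Some genes that meet these rules are not reported here.

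The alternatives were a pseudocount of 0.1, no filter on low values, a minimum mean of 5 FPKM, quantile normalization, median-of-ratios scaling, a replicate block, limma without the trend, each library left out in turn, a fit on the libraries of a line alone, an additive model of line and vector, and a minimum absolute log2 change of 1. Calls were also shared between lines at an unadjusted p under 0.01. Leaving out the H1975 libraries, using H1975 alone for AURKA, and subtracting the median change of neighbouring genes in H1975 were added after the data were seen. For an adjusted p less the neighbours, the limma change less that median was divided by the unchanged limma SE. Such a p leaves out the error of the median. Gene positions and GC content come from GENCODE 29 on GRCh38, matched by symbol, and 19220 of the 20028 distinct names in the table had a single position. Windows of 50 neighbouring genes in chromosome order were compared with 1000 shuffles of the genes. Counting and plotting used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

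The fit was tested on simulated data of 12218 genes with 50 changed genes per size. In the PC9 contrast 28% of genes changed by 0.25 on the log2 scale were called, 92% at 0.5 and 100% at 1. The shares were 36%, 100% and 100% in HCC827, 26%, 96% and 100% in H1975, 88%, 100% and 100% for the average, and 2%, 70% and 100% for the difference between lines. Of 12018 unchanged genes, between 0.033% and 0.083% were called. In the PC9 contrast camera called the 1 list that was raised and 0 of 20 unchanged lists. The simulated errors were independent between genes and the lists were drawn at random. This check therefore does not cover false calls of lists whose genes are correlated. The simulated errors also had the same spread in all 6 groups. In the data the mean SD between paired libraries was 0.0964 in HCC827 controls, against 0.0545 to 0.0663 in the other groups. The shares of false calls of genes therefore do not cover groups of unequal spread.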

Results

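Gene expression was measured by RNA-seq in PC9, HCC827 and H1975, lung cancer lines that carry activating mutations of EGFR, the receptor tyrosine kinase that osimertinib inhibits. H1975 also carries the gatekeeper substitution against which osimertinib was designed. All cells had been exposed to osimertinib in steps. The series asks what expression of ZNF263, a zinc finger transcription factor with a KRAB domain, changes in such cells, and its title concerns the response to EGFR-targeted therapy. Each line was sequenced with ZNF263 and with a control vector, with n = 2 libraries per group. Between 10672 and 10997 genes reached 1 FPKM in a library. At 1 FPKM the median gene stood for at least 119.1 reads in H1975 and at most 80.2 in PC9 and HCC827, but paired libraries of H1975 also differed by more than sampling at low read numbers.

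ZNF263 was higher in the libraries labelled ZNF263 in every line, and by less in HCC827. The gene lies on chromosome 16 at 3263800 to 3301401 (GRCh38, plus strand) and is protein-coding. Its level went from 9.33 ± 0.314 (SD, n = 2) to 39.1 ± 0.221 FPKM in PC9, from 12.5 ± 0.977 to 19.7 ± 0.093 FPKM in HCC827, and from 9.91 ± 0.399 to 39.5 ± 0.502 FPKM in H1975. Between 824 and 5956 reads stood behind each of these values. The log2 changes were 1.96 ± 0.061 (SE, limma adjusted p = 2.83e-09), 0.62 ± 0.061 (4.17e-05) and 1.89 ± 0.061 (5.95e-11). The rise in HCC827 differed from that in PC9 by -1.34 ± 0.087 on the log2 scale (limma adjusted p = 2.50e-06).

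**Figure D1:**
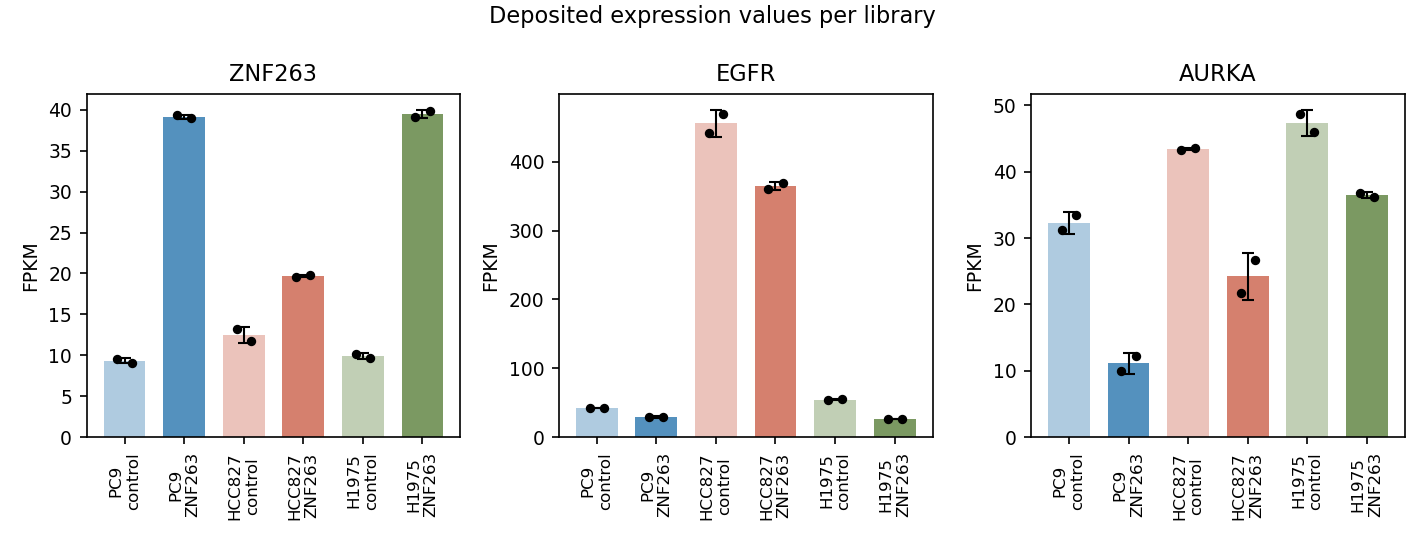
FPKM of ZNF263, EGFR and AURKA in each of the 6 groups, with points for single libraries and bars for the group mean with SD (n = 2). ZNF263 lay above its controls in every line, from 12.5 to 19.7 FPKM in HCC827 and from about 9.33 to 39.1 FPKM in PC9, while EGFR and AURKA lay below their controls.

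EGFR fell in each line. The gene lies on chromosome 7 at 55019021 to 55211628 (GRCh38, plus strand). In PC9 it went from 42.5 ± 0.5 to 29.4 ± 0.87 FPKM (SD, n = 2) and fell by 0.52 ± 0.049 (SE) on the log2 scale (limma adjusted p = 2.12e-05). In HCC827, in which EGFR is known to be amplified, it went from 456 ± 19.5 to 365 ± 5.96 FPKM and fell by 0.32 ± 0.049 (0.000834). In H1975 it fell by 1.01 ± 0.049 (1.99e-09), from 54.3 and 54.9 FPKM in the control libraries to 26.3 and 27.0 FPKM with ZNF263. The mean over the lines fell by 0.61 ± 0.028 (limma adjusted p = 5.84e-09), and the fall differed between lines (F test, limma adjusted p = 6.39e-06).

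AURKA, the mitotic kinase Aurora A, was also lower with ZNF263 in each line. The gene lies on chromosome 20 at 56369389 to 56392337 (GRCh38, minus strand). In PC9 it went from 32.3 ± 1.6 to 11.1 ± 1.56 FPKM (SD, n = 2) and fell by 1.46 ± 0.095 (SE) on the log2 scale (limma adjusted p = 9.89e-07). In HCC827 it went from 43.4 ± 0.141 to 24.2 ± 3.58 FPKM and fell by 0.82 ± 0.095 (0.000114), and in H1975 from 47.4 ± 1.93 to 36.5 ± 0.437 FPKM, a change of -0.37 ± 0.095 (0.00435). The mean over the lines fell by 0.88 ± 0.055 (limma adjusted p = 6.18e-08). AURKA was the 1 gene whose values were not whole numbers of reads in PC9 and in HCC827. In H1975, where every value was whole, the change was -0.37. Less the median change of neighbouring genes it was -0.20 (adjusted p = 0.0916 with the limma SE kept). The SE and p-values of that line use the spread shared with the values that were not whole, and a limma fit on its 4 libraries alone gave -0.37 ± 0.040 (adjusted p = 0.00139).

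Of the 24 measured members of the mitosis and AURKA module, none other than AURKA was called in PC9, where 0 rose, 1 fell and 23 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.974). In HCC827, 3 rose and 2 fell, among them TOP2A, the mitotic topoisomerase, which rose by 0.37 (limma adjusted p = 0.00408). In H1975, 8 rose and 7 fell, where KIF20A and CCNA2 rose by 0.66 and 0.50 (CCNA2 by 0.29 less its neighbours) and NEK2, a centrosomal kinase, fell by 0.50, more than AURKA. Less the medians of their neighbours NEK2 stood at -0.092 (limma adjusted p = 0.277) and AURKA at -0.198, which turns that order. The counts adjusted over the list alone were the same, and camera did not call the list (adjusted p = 0.824 and 0.797).

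DNMT1, the maintenance DNA methyltransferase on chromosome 19 at 10133345 to 10231286, was higher with ZNF263 in H1975 by 0.68 ± 0.045 (SE) on the log2 scale (limma adjusted p = 3.44e-08). It stood at 0.056 ± 0.045 in HCC827 (0.417) and -0.0083 ± 0.045 in PC9 (0.961), and the change differed between lines (F test, limma adjusted p = 1.63e-06). In H1975 the genes around DNMT1 had a median change of 0.37, and DNMT1 less that median stood at 0.31. STAT5A, a cytokine signal transducer on chromosome 17 at 42287547 to 42311943, rose by 0.43 ± 0.082 in HCC827 (0.00319) and 0.38 ± 0.082 in H1975 (0.00118, or 0.64 less its neighbours), and lay between 0 and 3 reads per library in PC9. STAT5B, its paralog at 42199168 to 42276707, stood at 0.0087 in PC9, -0.095 in HCC827 and -0.25 in H1975 (limma adjusted p = 0.00797), the last of which did not pass without H1975 control replicate 1 (-0.20, 0.0801) or less the median of its neighbours (-0.0055, 0.955). The STAT5 target list was called in no line, with camera adjusted p of 0.974 in PC9, 0.0596 in HCC827 and 0.626 in H1975. Of its 10 measured members 1 rose and 1 fell in PC9, 1 and 4 in HCC827, and 4 and 6 in H1975, against 2 and 1, 3 and 4, and 4 and 6 adjusted over the list alone.

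In PC9, several genes of secreted and surface proteins rose, airway mucins among them. MUC5B and MUC5AC, the gel-forming airway mucins, rose by 2.37 ± 0.087 and 1.64 ± 0.064 (SE) on the log2 scale, from 2.36 to 16.3 and from 2.65 to 10.3 FPKM (limma adjusted p = 7.51e-09 and 8.97e-09). SLPI, a protease inhibitor of airway secretions, rose by 1.94, C3, the central complement component, by 1.88, and the surface glycoprotein CEACAM6 by 2.36. Next to AURKA, the largest falls included those of VDR, the vitamin D receptor (fell by 1.36), the transcription factor FOXQ1 (fell by 0.97), PHLDA1 (fell by 0.91), the cytidine deaminase CDA (fell by 0.90) and CXCL8, the neutrophil chemokine (fell by 0.87). S100P and LYPD1 rose by 1.79 and 1.71, and AKAP12 and F2R, the thrombin receptor, fell by 0.88 and fell by 0.87.

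Genes of the secretory stress pathways fell together in PC9. In the unfolded protein response list, the chaperones and folding factors induced by stress of the endoplasmic reticulum, 0 of 20 measured members rose, 11 fell and 9 did not pass, and 14 fell adjusted over the list alone. HSPA5, the main chaperone of that compartment, fell by 0.62 ± 0.054 (SE) and HERPUD1 fell by 0.52. The camera adjusted p was 1.43e-10, with an adjusted p = 0.0544 with an estimated correlation. In the ATF4 response list, which serves amino acid supply under stress, 0 of 20 rose, 9 fell and 11 did not pass, and 14 fell adjusted over the list alone. ASNS, the asparagine synthetase, fell by 0.66 ± 0.054, and the secreted glycoprotein STC2 fell by 0.75 ± 0.068 (camera adjusted p = 2.03e-08, adjusted p = 0.0544 with an estimated correlation).

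MAPK output, the genes that ERK signalling induces, also fell in PC9 on balance, as 9 of 18 measured members fell, 2 rose and 7 did not pass (10 and 2 adjusted over the list alone). FOSL1, an AP-1 subunit, fell by 0.72 and CCND1, cyclin D1, fell by 0.30. The camera adjusted p was 1.15e-05, with an adjusted p = 0.127 with an estimated correlation. In the NF-kB and cytokine list 8 of 21 members fell, 1 rose and 12 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 0.0204, adjusted p = 0.211 with an estimated correlation). NFKB2 and RELB, subunits of the non-canonical pathway, fell by 0.71 and fell by 0.61, and the chemokine CXCL1 rose by 1.45. In the p53 target list 5 of 22 members fell, 0 rose and 17 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.00137, adjusted p = 0.0544 with an estimated correlation). GDF15, a stress cytokine, stood at -0.39 (limma adjusted p = 0.00686), and did not pass without PC9 control replicate 2 (-0.29, 0.105) or without PC9 ZNF263 replicate 2 (-0.37, 0.0543).

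Further lists rose in PC9. In the epithelial list 6 of 20 members rose, 0 fell and 14 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 5.04e-05, adjusted p = 0.0544 with an estimated correlation), with CDH1, E-cadherin, up by 0.99 ± 0.068 and the keratins KRT18 and KRT8 by 0.65 and 0.62. In the lung epithelial lineage list 4 of 13 rose, 0 fell and 9 did not pass (5 and 0 adjusted over the list alone), with MUC5B and MUC1 up by 2.37 and 0.71 (camera adjusted p = 0.0183, adjusted p = 0.386 with an estimated correlation). In the list of aldehyde dehydrogenases and drug efflux 5 of 13 rose, 1 fell and 7 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.0204, adjusted p = 0.127 with an estimated correlation), where CD44, a surface receptor for hyaluronan, rose by 0.58, ABCC3, an efflux transporter, rose by 0.39 and ALDH1A3 fell by 0.51. In the antigen presentation list 4 of 15 rose, 0 fell and 11 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 0.00656, adjusted p = 0.386 with an estimated correlation). HLA-C, a class I heavy chain, stood at 0.45 (limma adjusted p = 0.00381), and did not pass without PC9 control replicate 2 (0.33, 0.0629).

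In all, limma called 1430 of 12623 genes in PC9, 910 higher and 520 lower with ZNF263, and 45 of them changed by at least 1 on the log2 scale. The number of calls fell to 756 and 584 without PC9 control replicate 1 and 2, to 688 and 815 without PC9 ZNF263 replicate 1 and 2, and to 407 in a fit on the 4 PC9 libraries alone.

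In HCC827, surfactant protein genes rose and genes of amino acid stress and glucose use fell. SFTPB, surfactant protein B, rose by 1.56 ± 0.11 (SE) on the log2 scale, from 10.6 ± 0.246 to 33.5 ± 6.6 FPKM (SD, n = 2; limma adjusted p = 3.84e-06). SFTPA2 and SFTPA1, near-identical surfactant protein A genes between which reads may be divided uncertainly, rose by 2.26 and 1.41. The water channel AQP3 rose by 1.41, the surface glycoprotein CEACAM5 by 1.21, IRX3, KRT4 and CAVIN2 by 1.26, 1.20 and 1.17. G0S2, an inhibitor of lipolysis, fell by 1.84 ± 0.13, STC2 fell by 1.10, the stress sensor SESN2 fell by 1.09, and SLC2A1, the main glucose transporter of many tumours, fell by 0.96 ± 0.077. FSTL3, KRTAP2-3 and THBD, thrombomodulin, fell by 1.07, fell by 1.07 and fell by 0.94. The largest fall was that of SLX1B (-2.48 ± 0.556, limma adjusted p = 0.00828), which may share reads with its near-identical copy SLX1A and is uncertain. It did not pass without HCC827 control replicate 1 (-2.30, 0.0595) or without HCC827 ZNF263 replicate 1 (-2.29, 0.0723).

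Of the ATF4 response list, 19 of 20 measured members fell in HCC827, 0 rose and 1 did not pass, and 20 fell adjusted over the list alone. ASNS fell by 0.79 ± 0.054, PHGDH, the first enzyme of serine synthesis, fell by 0.91 ± 0.070, and DDIT4, an inhibitor of mTORC1 signalling, fell by 0.85. This list was called with either correlation (camera adjusted p = 8.41e-26, adjusted p = 0.0117 with an estimated correlation). In the hypoxia and glycolysis list 11 of 21 fell, 0 rose and 10 did not pass, with the same numbers adjusted over the list alone. NDRG1 fell by 0.81, LDHA, lactate dehydrogenase, fell by 0.46 and ADM, adrenomedullin, fell by 0.62 (camera adjusted p = 2.40e-11, adjusted p = 0.0301 with an estimated correlation).

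In the lung epithelial lineage list 10 of 13 members rose in HCC827, 0 fell and 3 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 6.96e-07, adjusted p = 0.0833 with an estimated correlation). Beside the surfactant genes, MUC1, a surface mucin, rose by 0.68. In the antigen presentation list 7 of 15 rose, 1 fell and 7 did not pass (10 and 1 adjusted over the list alone), with HLA-B up by 0.72, B2M, its light chain, by 0.37 and NLRC5, a transactivator of these genes, by 0.58. The camera adjusted p was 0.00797, with an adjusted p = 0.381 with an estimated correlation.

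Other lists fell in HCC827. In the NF-kB and cytokine list 7 of 21 fell, 0 rose and 14 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 4.05e-05, adjusted p = 0.0540 with an estimated correlation), where the cytokine LIF fell by 0.45 and TNFAIP3 fell by 0.58. In the mesenchymal list 7 of 19 fell, 1 rose and 11 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.0540 with an estimated correlation), where VIM, vimentin, fell by 0.63 ± 0.046, and the integrin chain ITGA5 fell by 0.46. In the MAPK output list 7 of 18 fell, 3 rose and 8 did not pass (9 and 4 adjusted over the list alone, camera adjusted p = 0.00159, adjusted p = 0.251 with an estimated correlation). DUSP5, an ERK phosphatase, fell by 0.90, CCND1 fell by 0.39 and FOSL1 fell by 0.57, while SPRY1, a feedback inhibitor of the same pathway, rose by 0.59.

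The remaining calls in HCC827 rested on few members or on the scaling. In the p53 target list 4 of 22 fell, 2 rose and 16 did not pass (7 and 2 adjusted over the list alone, camera adjusted p = 0.0338, adjusted p = 0.143 with an estimated correlation), with SESN2 and AEN among those that fell, and with median-of-ratios scaling the camera adjusted p was 0.0521. In the YAP/TEAD target list 5 of 16 fell, 1 rose and 10 did not pass (6 and 3 adjusted over the list alone, camera adjusted p = 0.0384, adjusted p = 0.299 with an estimated correlation), where FJX1 and F3, tissue factor, fell by 0.52 and fell by 0.50, and the median-of-ratios value was 0.0536. Among 26 ribosomal protein genes, 1 fell and 0 rose, and 0 were called adjusted over the list alone, with a median change of -0.085 (camera adjusted p = 0.000381, adjusted p = 0.596 with an estimated correlation).

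In HCC827 limma called 2386 of 12266 genes, 1596 higher and 790 lower, with 26 changed by at least 1 on the log2 scale. The count was 1035 without HCC827 ZNF263 replicate 1 and 634 in a fit on the 4 HCC827 libraries alone. The share of higher calls was 66.9% with values as deposited, 45.0% with median-of-ratios scaling and 50.3% with quantile normalization.

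In H1975, expression changed far more widely, with a loss of epithelial transcripts and a gain of several collagens and other matrix genes. EPCAM, the epithelial adhesion molecule, fell by 2.79 ± 0.075 (SE) on the log2 scale, from 225 ± 6.83 to 31.7 ± 0.714 FPKM (SD, n = 2; limma adjusted p = 1.71e-11), the tight junction gene CLDN7 fell by 2.73, and CDH1 fell by 2.23. COL1A2 and COL12A1, collagen chains, rose by 3.43 ± 0.080 and 3.49 ± 0.066, from 14.6 to 166 (14.55 and 166.4) and from 8.53 to 106 (105.8) FPKM. MGP, a matrix inhibitor of calcification, rose by 3.78, the monocyte chemokine CCL2 by 3.75, CHI3L1 by 3.51, S100A4 by 3.48, the adenosine receptor ADORA2A by 3.44 and COL8A1 by 3.37. The antimicrobial RNASE7 fell by 4.08, the interferon-induced IFI27 fell by 3.81, SPINK1 fell by 3.76, PTGS2, cyclooxygenase 2, fell by 3.66, ALDH1A3 fell by 3.496, and MYEOV, S100A2 and the collagenase MMP1 fell by 3.19, fell by 3.05 and fell by 3.03.

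In the epithelial list 19 of 20 measured members fell in H1975 and 1 rose, with the same numbers adjusted over the list alone and a median change of -1.54. ESRP1, a splicing regulator of epithelial cells, fell by 2.69, and the exception, KRT8, stood at 0.24 (limma adjusted p = 0.00696, and 0.75 less its neighbours). The list was called with either correlation (camera adjusted p = 3.72e-10, adjusted p = 0.0289 with an estimated correlation). In the mesenchymal list 9 of 19 rose, 3 fell and 7 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.0370, adjusted p = 0.255 with an estimated correlation). SPARC, TAGLN and LOX, products of matrix-forming cells, rose by 2.40, 2.97 and 2.44. Beside these, 6 of 9 measured fibroblast markers rose and 3 fell, and the list was not called (camera adjusted p = 0.138), since COL5A1 and COL6A1 rose by 2.74 and 1.76 with COL1A2 and MGP whereas FBLN1, LUM and COL1A1 fell by 1.38, fell by 1.33 and fell by 0.71, of which LUM and COL1A1 were singled out after their values were seen.

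Interferon-stimulated genes fell in H1975, as 22 of 24 measured members fell and 2 rose, with the same numbers adjusted over the list alone. The antiviral enzymes OAS1 and OAS2 fell by 2.30 and fell by 2.17, and RSAD2 fell by 1.08, or by 0.65 less the median of its neighbours (camera adjusted p = 1.54e-07, adjusted p = 0.427 with an estimated correlation). Antigen presentation moved the other way, as 13 of 15 members rose and 2 fell, again with the same numbers adjusted over the list alone (camera adjusted p = 0.00109, adjusted p = 0.427 with an estimated correlation). HLA-B rose by 1.78, HLA-C by 1.049 and TAPBP, tapasin, by 0.91. These genes lie on the short arm of chromosome 6, where neighbouring genes rose too, and less the median of its neighbours HLA-B stood at 1.40, HLA-C at 0.70 and TAPBP at 0.40, while the median of the list went from 0.82 (0.815) to 0.30.

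In the p53 target list 15 of 22 fell in H1975, 2 rose and 5 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.000824, adjusted p = 0.0685 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, fell by 1.999, PHLDA3 fell by 2.01 and MDM2 fell by 0.76. In the unfolded protein response list 10 of 20 rose, 2 fell and 8 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.0370, adjusted p = 0.466 with an estimated correlation). XBP1 rose there by 1.47 (0.98 less its neighbours) and HYOU1 by 0.61 (0.40 less its neighbours). In the NF-kB and cytokine list 12 of 21 rose, 4 fell and 5 did not pass (13 and 4 adjusted over the list alone, camera adjusted p = 0.0424, adjusted p = 0.427 with an estimated correlation), where CXCL1 rose by 2.19 and IL1A fell by 1.37.

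**Figure D2:**
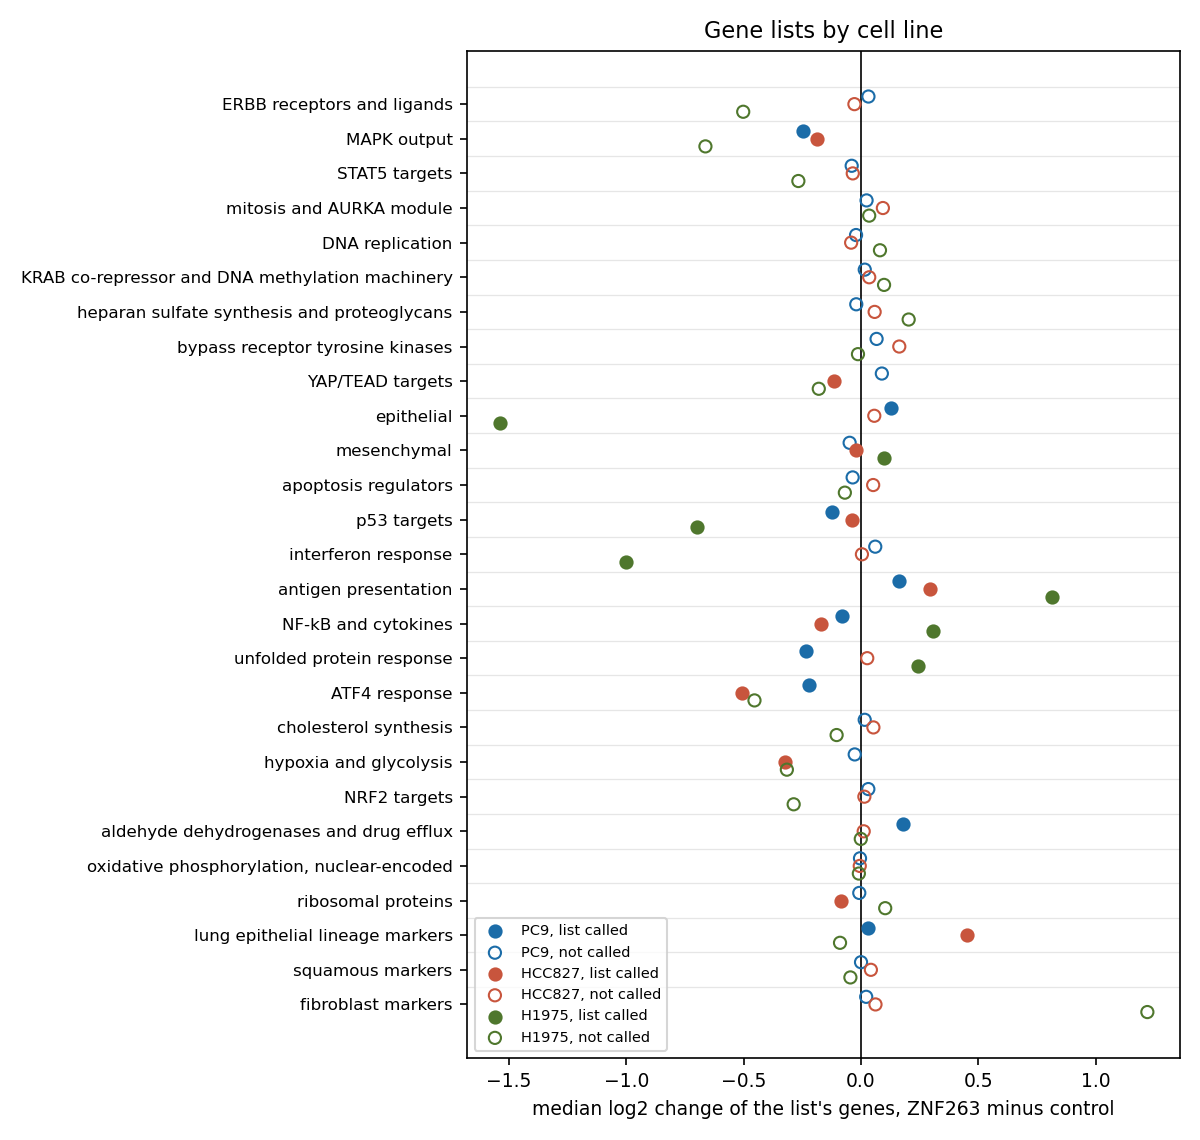
Median log2 change of the measured genes of each list, ZNF263 minus control, by cell line, with filled points where camera called the list at its preset correlation. The epithelial list lay at -1.54 in H1975 and at 0.13 in PC9, and the lung epithelial lineage list was highest in HCC827, at 0.45.

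Part of the change in H1975 followed chromosomal position. Of 232 windows of 50 neighbouring genes, 45 had a median change beyond 0.3 in either direction, against at most 1 in 1000 shuffles of the genes, while 0 windows did in PC9 and 0 in HCC827. The SD of the window medians was 0.244 in H1975, against at most 0.080 in the shuffles, and the far smaller 0.032 in PC9 and 0.040 in HCC827 also lay above their shuffles (at most 0.024 and 0.032). Examples of runs in H1975, chosen after the values were seen, are those raised along chromosome 22 from 17084954 to 44172949 (4 windows at 0.40 to 0.53 and 1 at 0.25), on the short arm of chromosome 6 from 291630 to 44253888 (5 windows at 0.36 to 0.625 and 1 at 0.286), on chromosome 11 from 2883213 to 45906465 (3 windows, 0.36 to 0.52), on X from 77826364 to 152973480 (3 windows, 0.56 to 0.76) and on chromosome 19 from 10221433 to 19683509 (4 windows, 0.495 to 0.64). Examples of lowered runs lay on chromosome 8 from 73780097 to 133571940 (3 windows, -0.69 to -0.33), chromosome 12 from 48766194 to 71927248 (4 windows, -0.48 to -0.30), chromosome 2 from 217730 to 38929072 (3 windows, -0.42 to -0.305) and chromosome 19 from 52453576 to 57559863 (2 windows, -0.73 to -0.57). EGFR lay outside such a block, with a median of -0.022 among its neighbours. The epithelial list stood at -1.50 and the interferon list at -0.93 (-0.925) less the neighbours' medians.

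**Figure D3:**
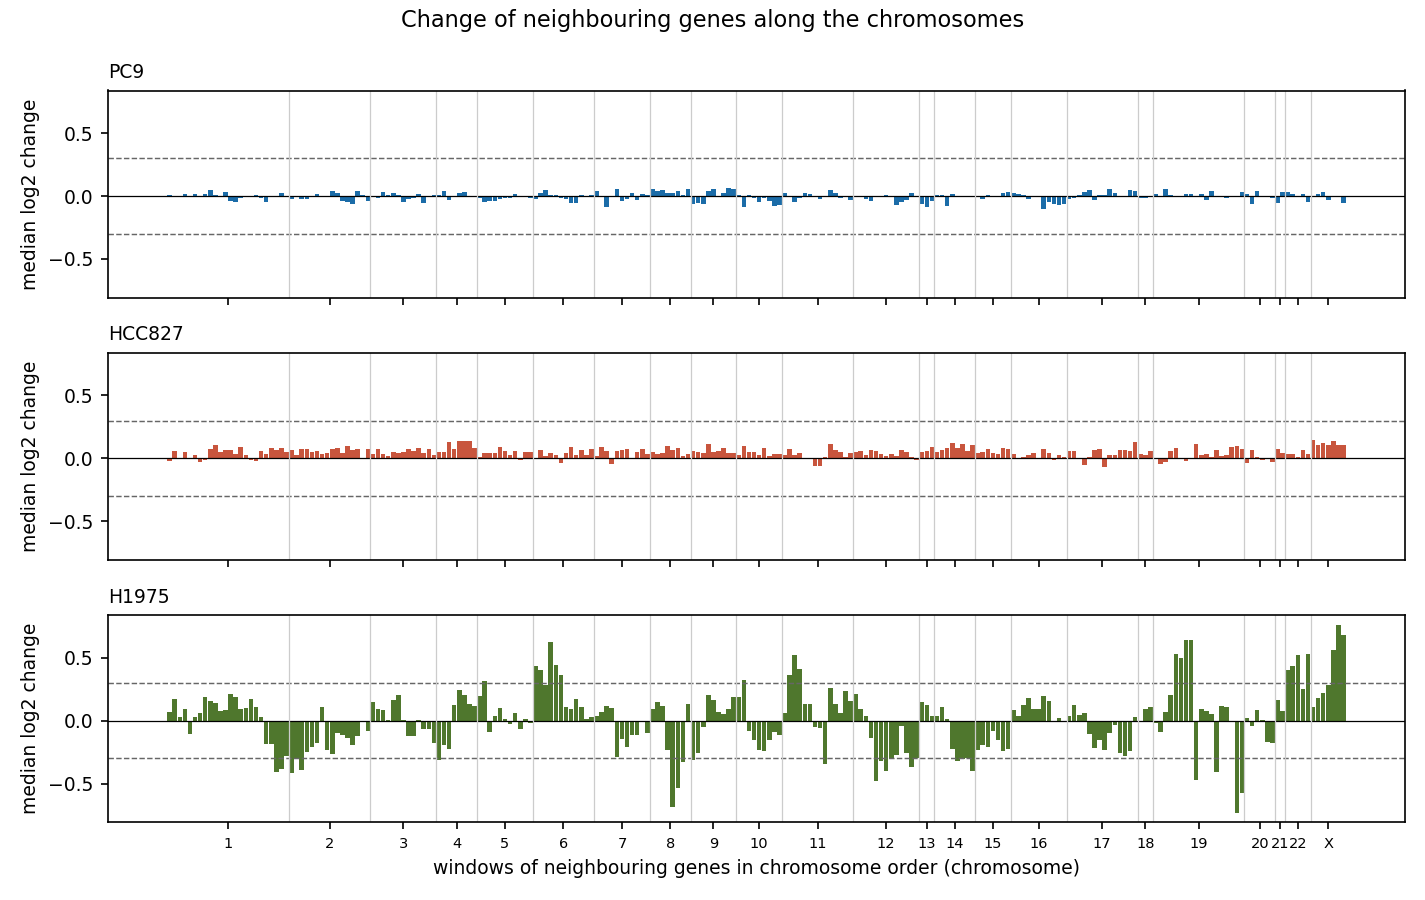
Median log2 change, ZNF263 minus control, of windows of 50 neighbouring genes in chromosome order in each line, with dashed lines at 0.3 in either direction. In H1975, 45 of 232 windows lay beyond the lines, in blocks such as that on chromosome 22, and in PC9 and HCC827 0 windows did.

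In H1975 limma called 7870 of 12258 genes, 3937 higher and 3933 lower, with 1059 changed by at least 1 on the log2 scale. Less the median of neighbouring genes, 6952 of 12176 genes with a position were called, 5677 of them also called without that step. The SD of the changes went from 0.612 to 0.567 and the number changed by at least 1 from 1059 to 884, so most of the spread remained.

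Averaged over the lines, some collagen genes rose and some genes of the MAPK programme fell. Genes are ranked here by average change among those whose libraries with ZNF263 lay beyond both controls in every line. Next to ZNF263 (1.49 ± 0.035), the largest average rises were those of PDZK1IP1 (1.41 ± 0.099 SE), TP53I11 (1.33 ± 0.048) and the steroid-reducing enzyme AKR1C3 (1.29). COL12A1 (1.27), the actin-binding TAGLN (1.25), the collagen chain COL6A2 (1.25) and the mannosidase MAN1A1 (1.20) followed. PKIB, an inhibitor of protein kinase A, fell by 1.36 ± 0.052, MYEOV fell by 1.27, the chromatin protein HMGA2 fell by 1.09, DUSP5 fell by 0.96, FOSL1 fell by 0.94, OAS1 fell by 0.93 and OTUB2 fell by 0.90. The limma adjusted p of these genes lay between 6.94e-11 and 1.89e-07. The single-line changes of several of them were small, such as those of COL12A1 in PC9 (0.12, limma adjusted p = 0.282) and OAS1 in HCC827 (-0.25, 0.0958). AKR1C3, COL12A1, TAGLN, MYEOV, OAS1 and OTUB2 were not called in every line.

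**Figure D4:**
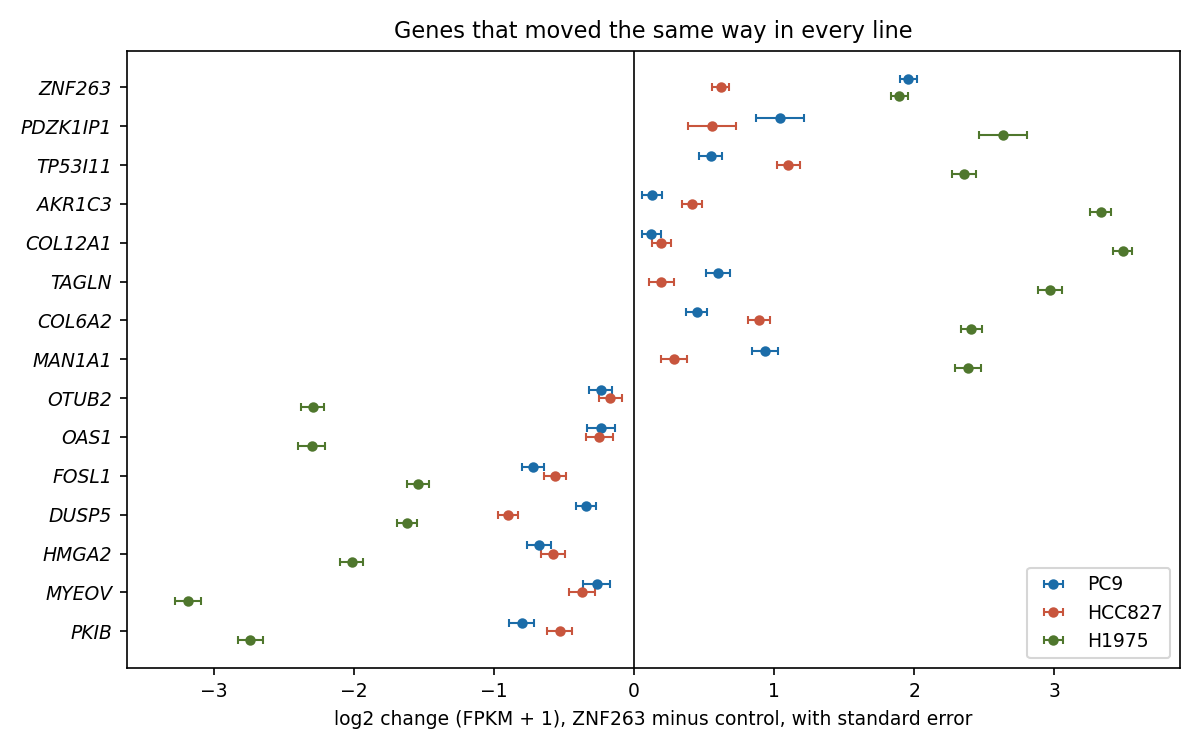
Log2 change with its standard error in each line for genes with the largest average rises and falls that moved the same way in every line. H1975 lies farthest from 0 for each of them except ZNF263, whose change was 1.96 in PC9 and 1.89 in H1975.

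On average the ATF4 response list had 16 of 20 members down, 0 up and 4 not passing (18 and 0 adjusted over the list alone, camera adjusted p = 8.50e-09, adjusted p = 0.0605 with an estimated correlation), and DDIT3, a stress transcription factor, fell by 0.82. In H1975 itself 7 members rose and 12 fell, the same adjusted over the list alone, and camera did not call the list (adjusted p = 0.138). In the epithelial list 15 of 20 fell and 3 rose (16 and 3 adjusted over the list alone, camera adjusted p = 4.80e-07, adjusted p = 0.0408 with an estimated correlation), and in the p53 target list 15 of 22 fell and 0 rose, the same adjusted over the list alone (8.55e-06, adjusted p = 0.0408 with an estimated correlation). The epithelial fall came from H1975, since that list rose in PC9 and had 5 members up and 2 down in HCC827 (6 and 2 adjusted over the list alone). In the interferon list 16 of 24 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 5.04e-06, adjusted p = 0.412 with an estimated correlation). H1975 carried that fall, since 1 interferon gene rose and 0 fell in PC9 (0.356) and 3 rose and 4 fell in HCC827 (0.507), the same adjusted over the list alone. In the antigen presentation list 12 of 15 rose and 0 fell (12 and 1 adjusted over the list alone, camera adjusted p = 9.14e-05, adjusted p = 0.299 with an estimated correlation), with HLA-B and HLA-C up by 0.94 and 0.59. MAPK output (11 of 18 fell, 3 rose) had a camera adjusted p of 0.00131 and an adjusted p = 0.299 with an estimated correlation, with CCND1 and PHLDA1 down (fell by 0.88 and fell by 0.82), and 11 fell and 4 rose adjusted over the list alone. In H1975, 7 MAPK output genes rose and 11 fell, the same adjusted over the list alone, without a call (camera adjusted p = 0.0743), and neither epithelial genes in HCC827 (0.379) nor hypoxia genes in PC9 (0.974) and H1975 (0.282) were called. Hypoxia and glycolysis (12 of 21 fell, 2 rose, and 12 and 3 adjusted over the list alone) had 0.0032 and an adjusted p = 0.282 with an estimated correlation, although CA9, a hypoxia-induced carbonic anhydrase, rose by 1.17. Fibroblast markers (6 of 9 rose, 3 fell, the same adjusted over the list alone) had 0.0338 and an adjusted p = 0.248 with an estimated correlation.

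For the average limma called 6458 of 12218 genes, 3536 higher and 2922 lower, with 46 changed by at least 1 on the log2 scale. The share of higher calls was 54.8% (54.75) with values as deposited, 47.9% with median-of-ratios scaling and 49.2% with quantile normalization. An additive model of line and vector called 1048 genes, and the mean of PC9 and HCC827 alone, a choice made after the data were seen, called 2320.

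Of the genes called in 2 lines, more had moved the same way than independent lists would share. PC9 and HCC827 shared 282 higher genes against 113 expected (113.4; Fisher's exact test, 1-sided, adjusted p = 3.83e-53) and 109 lower genes against 32.3 (3.03e-30). PC9 and H1975 shared 349 higher against 281 (280.6; 4.92e-07) and 224 lower against 160 (160.2; 1.80e-09), and HCC827 and H1975 shared 636 higher against 511 (511.2; 2.75e-12) and 376 lower against 254 (253.6; 2.04e-20). Genes higher in PC9 and lower in HCC827 numbered 47 against 56.4, and the other 5 pairings of opposite directions also lay below expectation. Fisher's test treats genes as independent, and the calls of all lines use the same spread per gene. The expected numbers leave out both, so the adjusted p may be too small. The overlaps were not repeated with the other scalings. In every line 134 genes rose, among them COL6A1, and 61 fell, among them FOSL1, DUSP5 and HMGA2, against 36.5 and 10.4 for independent lists. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.23 between PC9 and HCC827, 0.067 between PC9 and H1975 and 0.073 between HCC827 and H1975 (Spearman's correlation 0.24, 0.067 and 0.077).

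The difference between ZNF263 and control libraries varied between lines for many genes, mostly through H1975. COL12A1 changed by 3.36 ± 0.095 (SE) more in H1975 than in PC9, and BMP4, a secreted growth factor, rose by 0.66 in PC9, fell by 0.47 in HCC827 and rose by 3.14 in H1975. MAL2 and CD24, apical and surface proteins of epithelial cells, rose by 1.14 (1.135) and 0.50 in PC9 and fell by 2.62 and fell by 2.41 in H1975. The P-cadherin gene CDH3 and the matrix genes COL8A1 and ADAMTS9 differed in the same comparison by -2.57, 3.35 (3.355) and 2.85. The epithelial list differed between H1975 and PC9 (camera adjusted p = 3.38e-14, adjusted p = 0.0118 with an estimated correlation), with 20 of 20 members lower in the difference. The ATF4 list fell further in HCC827 than in PC9 (camera adjusted p = 1.07e-10, adjusted p = 0.0382 with an estimated correlation). The F test called 7385 of 12218 genes, and 937 differed between PC9 and HCC827 in a fit without the H1975 libraries.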

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

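The tests of fibroblast RNA and the fit without H1975 were chosen only after the results were seen. The results here were singled out because the difference between ZNF263 and control libraries varied between cell lines by a test of that variation. Most genes named for the lines or the average were chosen by their changes in the same data. A large share of calls among them follows from that choice. The F test called 7385 of all 12218 genes (60.4%). Among the named genes its limma adjusted p was 1.43e-10 for each of COL12A1, BMP4, MAL2, CD24, CDH3 and COL8A1, 1.72e-10 for ADAMTS9, 5.22e-08 for ZNF263, 6.39e-06 for EGFR, 1.63e-06 for DNMT1, 0.0181 for STAT5A and 4.62e-05 for AURKA, and of the 263 genes named for the lines or the average, some of these included, 246 were called. STAT5A held between 0 and 3 reads per library in PC9, too few to show a change there. Camera called 7 lists for the difference between HCC827 and PC9, of which the ATF4 response (1.07e-10), hypoxia and glycolysis (2.26e-09) and mesenchymal (9.20e-05) lists kept an adjusted p of 0.0382 each with an estimated correlation. It called 8 lists between H1975 and PC9 and 8 between H1975 and HCC827, with the epithelial list at 3.38e-14 and 1.14e-10 and adjusted p = 0.0118 and 0.0254 with an estimated correlation.

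The pattern behind most of these differences is the size of the change in H1975. The tables argue against fibroblasts in the libraries with ZNF263, since COL3A1 reached a mean of 0.308 FPKM beside 166.4 FPKM of COL1A2, and COL1A1 and LUM fell. They allow a sub-line with other chromosome copy numbers, as 45 windows of neighbouring genes had a median change beyond 0.3. Such a sub-line may have arisen when cells were selected in osimertinib or after the vector was introduced. A trend with GC content leaves 46 such windows and so does not account for them. The shuffles of the genes show only that neighbours changed together, and joint regulation of neighbouring genes would pass them too. Copy number itself was not measured. Replacement by cells of another line or type stays open: 100 genes at least 10-fold higher in H1975 controls than in both other lines had a median change of -0.841 (95% bootstrap interval -1.30 to -0.395), with 64 falling and 20 rising, although the 2 H1975 groups correlated at r = 0.951 across genes, against at most 0.863 between groups of different lines. Those 100 genes were chosen by high values in the same control libraries, which favours falls. The bootstrap resampled genes as if they were independent. Less the medians of neighbouring genes, the SD of the changes went from 0.612 to 0.567 and the genes changed by at least 1 from 1059 to 884. The blocks thus leave most of the change. An effect of ZNF263 cannot be separated in this design from other differences between the 2 H1975 groups, such as those of a sub-line. The same limit holds for the groups of PC9 and HCC827, since the libraries of a group are not known to come from separate cultures.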

How the results depend on the processing

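The fits without the H1975 libraries, on H1975 alone and less the neighbouring genes were chosen after the results were seen. The rise of ZNF263 in PC9 (1.93 to 2.06), HCC827 (0.54 to 0.69) and H1975 (1.85 to 1.98), the average fall of EGFR (-0.64 to -0.42) and that of AURKA (-0.93 to -0.37) kept their direction and their side of the threshold with these alternatives. Less the neighbouring genes, ZNF263 in H1975 stood at 1.825, and AURKA in H1975 at -0.198 with a limma adjusted p of 0.0916, which loses the call with the spread shared by all groups. The values nearest 0 for EGFR and AURKA come from PC9 with HCC827 (-0.42) and from a fit on the 4 H1975 libraries alone (-0.37 ± 0.040 SE, limma adjusted p of 0.00139). The counts of calls in PC9 ranged from 584 to 1898 with a library left out, and in HCC827 from 1035 to 3107, where a group with a lone library was assumed to vary like the others. They were 407 and 634 in fits on a line alone, which have fewer residual degrees of freedom. A minimum absolute log2 change of 1 left 45 genes in PC9, 26 in HCC827, 1059 in H1975 and 46 for the average. The additive model, which counts differences between lines as noise, called 1048 genes for the average. Without H1975 the average called 2320 genes and the difference between lines 937, and less the neighbouring genes H1975 called 6952. Lists called went from 34 to 5 with an estimated correlation, and to 33 with median-of-ratios scaling. Genes called in all 3 lines went from 195 to 223 at the unadjusted p. The other counts stayed within 1.5 times under a pseudocount of 0.1, both filters, both scalings and no trend. In HCC827 the scalings moved the median change of all genes from 0.045 to -0.0041 and -0.0025, and 1861 and 1760 of the 2386 calls were shared. Of the comparisons of named genes with a library left out, 215 no longer passed and 5062 were as before, and of those under other settings 81 and 2927. Many of the left-out libraries belonged to another line than the contrast, and these act on it mainly through the shared spread. Genes uncalled both times also count as before. The numbers as before therefore do not measure how calls hold when a library of the same line is lost. The direction turned in 2 cases, neither called: DNMT1 in HCC827 with median-of-ratios scaling (-0.012) and STAT5B in PC9 without PC9 control replicate 1 (-0.052). The causes were not tested. Libraries with the same number did not deviate together (correlations of 0.037, 0.089 and -0.044 in PC9, HCC827 and H1975), so the numbers were not taken to pair them. With the replicate block 1364, 2262 and 7850 genes were called in the lines, 6524 for the average and 7369 for the difference, and 33 lists, with 1235, 2086, 7686 and 6241 calls shared with the fits without it.

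Among 100 of the 108 splits of the libraries within their lines, the real split gave the largest count for the average, 6458 against at most 5880, so 1 of 100 reached it. The 2 other splits drawn that keep the groups whole, with the labels of 1 line swapped, gave 5836 and 5880. A large count therefore does not show that the lines changed alike. Splits that mix a group gave at most 4873, with a median of 2. Their counts lay either at 50 and fewer or at 3107 and more. Depth limits genes of low expression most, and at 1 FPKM the PC9 and HCC827 libraries held between 64.9 and 80.2 reads of the median gene.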

Other observations

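The test of reads shared between genes was chosen only after the AURKA values were seen. Among ERBB receptors and ligands, TGFA and ERBB3 moved in different directions in the lines. TGFA, an EGFR ligand, rose by 1.34 ± 0.084 (SE) in PC9 and fell by 2.37 ± 0.084 in H1975 (limma adjusted p = 8.80e-07 and 1.16e-10). ERBB3, a partner receptor, fell by 0.69 in PC9 and fell by 1.97 in H1975 but rose by 0.58 in HCC827, and LRIG1, an inhibitor of these receptors, rose by 2.29 in H1975. Of 12 measured members, 3 rose and 3 fell in PC9 and in HCC827 (3 and 4 adjusted over the list alone in each), and 3 rose and 8 fell in H1975, the same adjusted over the list alone (camera adjusted p = 0.974, 0.589 and 0.111). Other receptors of bypass signalling moved in H1975, where MERTK fell by 2.60, MET fell by 1.09, FGFR1 rose by 1.34 and PDGFRB rose by 1.22 (5 of 14 rose and 6 fell, the same adjusted over the list alone, camera adjusted p = 0.860). The proteoglycans SDC3 and SDC2 rose there by 1.71 (1.705) and 1.89, EXT1 fell by 1.04 (or by 0.61 less its neighbours), and in HCC827 SDC1 rose by 0.60 (heparan sulfate list of 23, camera adjusted p = 0.219 in H1975, where 11 rose and 7 fell, and 0.824 in HCC827, where 5 rose and 2 fell, against 12 and 7, and 6 and 3 adjusted over the list alone).

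Further lists called in no line are given with their camera adjusted p for the average. DNA replication (8 of 24 rose, 6 fell) had 0.927, the KRAB co-repressor and DNA methylation list (7 of 21 rose, 4 fell) had 0.746, bypass receptor tyrosine kinases (6 of 14 rose, 6 fell) had 0.927, apoptosis regulators (4 of 23 rose, 8 fell) had 0.254, cholesterol synthesis (6 of 20 rose, 7 fell) had 0.855, NRF2 targets (4 of 21 rose, 9 fell) had 0.208, nuclear-encoded oxidative phosphorylation (3 of 23 rose, 7 fell) had 0.473, and squamous markers (3 of 9 rose, 3 fell) had 0.627. Adjusted over the list alone the numbers were the same except for the KRAB list (8 rose) and NRF2 targets (10 fell). TRIM28, the co-repressor that KRAB domains recruit, fell by 0.86 in H1975, where the genes around it had a median change of -0.44 and TRIM28 less that median stood at -0.42. Too few genes were measured to test neuroendocrine (4), immune (3) and endothelial (2) markers, of which SCG2 rose by 2.73 (2.735) and CD79A fell by 2.76 in H1975. Mitochondrially encoded genes were not measured, and 11 histone genes were measured in PC9 alone, of which 0 were called by limma.

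AURKA values differ in kind from those of other genes. In HCC827 its control libraries held 2289.0 and 2194.0 reads, in units carried over from H1975, and those with ZNF263 held 1118.735 and 1384.432, which are 0.265 and 0.432 away from whole numbers, while in PC9 no whole numbers up to 300000 reads fitted its values. Fractional counting of shared reads would touch other genes. Of 14280 HCC827 genes, 14279 were whole within 0.03 reads with multiples of up to 12 allowed, AURKA being the exception. Without a multiple 13184 were whole, and elsewhere a multiple lets simple fractions of a read pass as whole. Fractional counting is therefore argued against only for those 13184 genes, and the test cannot exclude it elsewhere. A limit of resolution is argued against, since the 3134 other genes with 1000 to 3000 reads lay at most 1e-04 from a whole number. The same multiples were allowed there. It stays open whether these cells come from another processing step that the sources used here do not record, and the H1975 change (-0.37, or -0.20 less its neighbours) is the one whose size does not depend on them, while its p-values in the shared fit do.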
